A study of Mus musculus with 10 samples.

How the data were processed

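RNA abundance was measured by RNA-seq of heart tissue from male mice born to dams that received either anti-Müllerian hormone (AMH) or phosphate-buffered saline during pregnancy. Prenatal AMH exposure, abbreviated PAMH in the labels, is used as a mouse model of polycystic ovary syndrome. The labels gave 5 control and 5 PAMH samples, all wild type, with RNA extracted by the Trizol method and libraries made with a VAHTS universal kit. Groups and replicate numbers were taken from the sample titles, and each column of the table was matched to a sample by the column name in the sample's description. The labels describe male offspring but do not tie each sample to an animal, a litter or a dam, so the p-values measure the spread between these samples, which may in part be technical or shared within litters.

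The authors deposited a single table of FPKM (read fragments normalised to transcript length and to the total of mapped fragments) for 55335 Ensembl genes in the 10 samples. Per the submitters' processing notes, the tools used in the study included FastQC 0.11.9, Trimmomatic 0.38, HISAT2 2.2.1, HTSeq 0.13.5, R 3.4.1 and DESeq2 1.18.1 with the genome build mm10, and the notes assign no step to a tool. The tool that gave the FPKM, the gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The deposited FPKM were checked for how they had been built. Of 13058 genes with several annotated transcripts 98.4% had values with more than 6 decimals, against 0.825% of 6668 genes with a single annotated transcript. The gene values had therefore been computed from values of several transcripts. Whole reads could not be recovered from such values, and the sequencing depth of the samples is unknown. No interval or detection limit that needs a read count is given, and a value of 0 is reported only as listed at 0. The FPKM summed to between 654350 and 717453 per sample, and no 2 columns were identical.

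Gene symbols, gene types and coordinates (1-based, build GRCm38, which is mm10) came from the GENCODE release vM21 annotation, in which 55154 of the identifiers were found and 181 were not. FPKM were transformed as log2(FPKM + 1), so a log2 fold change is on this scale and understates the change of genes with low FPKM. Genes with a mean of at least 1 FPKM over the 10 samples were tested (9439 genes) with limma 3.58.1 in R 4.3.3, using a group term, empirical Bayes with an intensity trend, 2-sided tests and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. Standard errors (SE) are those of limma. Gene lists were fixed before the data were examined. Of the 63 lists, which covered cardiac stress, metabolism, protein turnover, matrix, immune response, hormone action, the clock and markers of cell types, 51 had at least 5 tested members. They were compared with all other tested genes by camera with a preset correlation of 0.01, by camera with a correlation estimated for each list, and by fry, which tests each list by itself. Differences in sample measures were tested by exact 2-sided permutation tests over 8 measures.

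The genes to be named were also set by a rule fixed before the data were examined. It took the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose values in the groups did not overlap and that had a symbol not of a predicted gene. It added the 4 members with the smallest p in the direction of each list called by camera, and a fixed panel of cardiac, metabolic and hormone receptor genes. Genes named outside this rule are identified as chosen after their values were seen. Some genes that the rule selects are not reported here.

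The procedure was tested on simulated data with the means and spread of the 9439 tested genes. For the comparison of 5 with 5 samples it recovered 97% of 100 genes given a log2 change of 1 and 60% of 100 genes given a log2 change of 0.5, and 4 of its 161 calls (2.48%) were false. The simulated noise was independent between genes and had the same spread in every sample. These rates therefore need not hold for the real data. Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, rescaling each sample to the same sum (as in TPM), median ratio scaling, quantile normalization, sample weights, robust empirical Bayes, the replicate number as a block, and omission of each sample in turn. A further 5 settings were chosen after seeing the data. They were omission of the mitochondrial genes with their nuclear copies, omission of PAMH replicates 4 and 5, protein-coding genes only, and removal of each sample's trend on transcript length and GC content (loess, span 0.5), with and without centring each sample. The form of the trend removal without centring was introduced after the centred form had been seen, because centring sets the level of each sample. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.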

Results

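The transcriptomes of hearts from 5 control and 5 PAMH male mice were compared to ask which cardiac genes differ in male offspring after prenatal exposure to anti-Müllerian hormone. The deposited FPKM summed to 704433 ± 10244 in control and 681750 ± 24073 in PAMH samples (mean ± SD, n = 5 each), and the read depth behind them is unknown. Between 16113 (PAMH replicate 4) and 21097 genes had a value above 0. The genes of the mitochondrial genome held a large part of each sum, 56.2% ± 0.611 in control and 54.2% ± 1.83 in PAMH hearts (SD, n = 5 each; exact permutation p = 0.0317, adjusted p = 0.127 over 8 sample measures). PAMH replicate 4 stood apart, with a hemoglobin sum of 859 FPKM against 97.1 to 249 FPKM in the other PAMH samples. Its rank correlation with the median sample was 0.946, against at least 0.973 in the others. PAMH replicate 5 had the next fewest genes above 0 (18037) and the next lowest rank correlation (0.973). PAMH replicate 3 lay between the groups. On the 1126 genes called without this sample its median position was 0.40 on a scale from 0 at the control mean to 1 at the PAMH mean, where the other PAMH samples, placed likewise, lay at 0.84 to 0.99 and the controls at -0.0023 to 0.22. It was on the PAMH side of all 5 controls for 56.3% of these genes, and its Pdk4 (17.9 FPKM) and Ucp3 (2.69 FPKM) were the lowest of all 10 samples.

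PAMH hearts differed from control hearts in 584 of 9439 genes, of which 467 were higher and 117 lower (limma, adjusted p under 0.05), and without PAMH replicate 3 in 1126 genes (979 higher, 147 lower). The largest fall was in Pdk4, a kinase that inhibits pyruvate dehydrogenase and so limits glucose oxidation (chromosome 6, 5483351 to 5496309), from 208 ± 74.8 to 27.0 ± 8.60 FPKM (SD, n = 5 each; log2 fold change -2.88, SE 0.24, adjusted p = 0.000115). Angptl4, a secreted inhibitor of lipoprotein lipase, fell from 3.81 ± 1.61 to 0.482 ± 0.440 FPKM, the mitochondrial carrier Ucp3 from 12.8 ± 3.86 to 3.28 ± 0.463 FPKM, and Txnip, which restrains glucose uptake, from 161 ± 18.8 to 55.2 ± 7.52 FPKM. Each of these 4 genes had all PAMH values below all control values. The rule that took the largest changes required such a separation, which 797 of all 9439 tested genes (8.44%) had. Only 16 genes rose and 6 fell by at least 1 on the log2 scale, and the median size of a called change was 0.42.

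**Figure D1:**
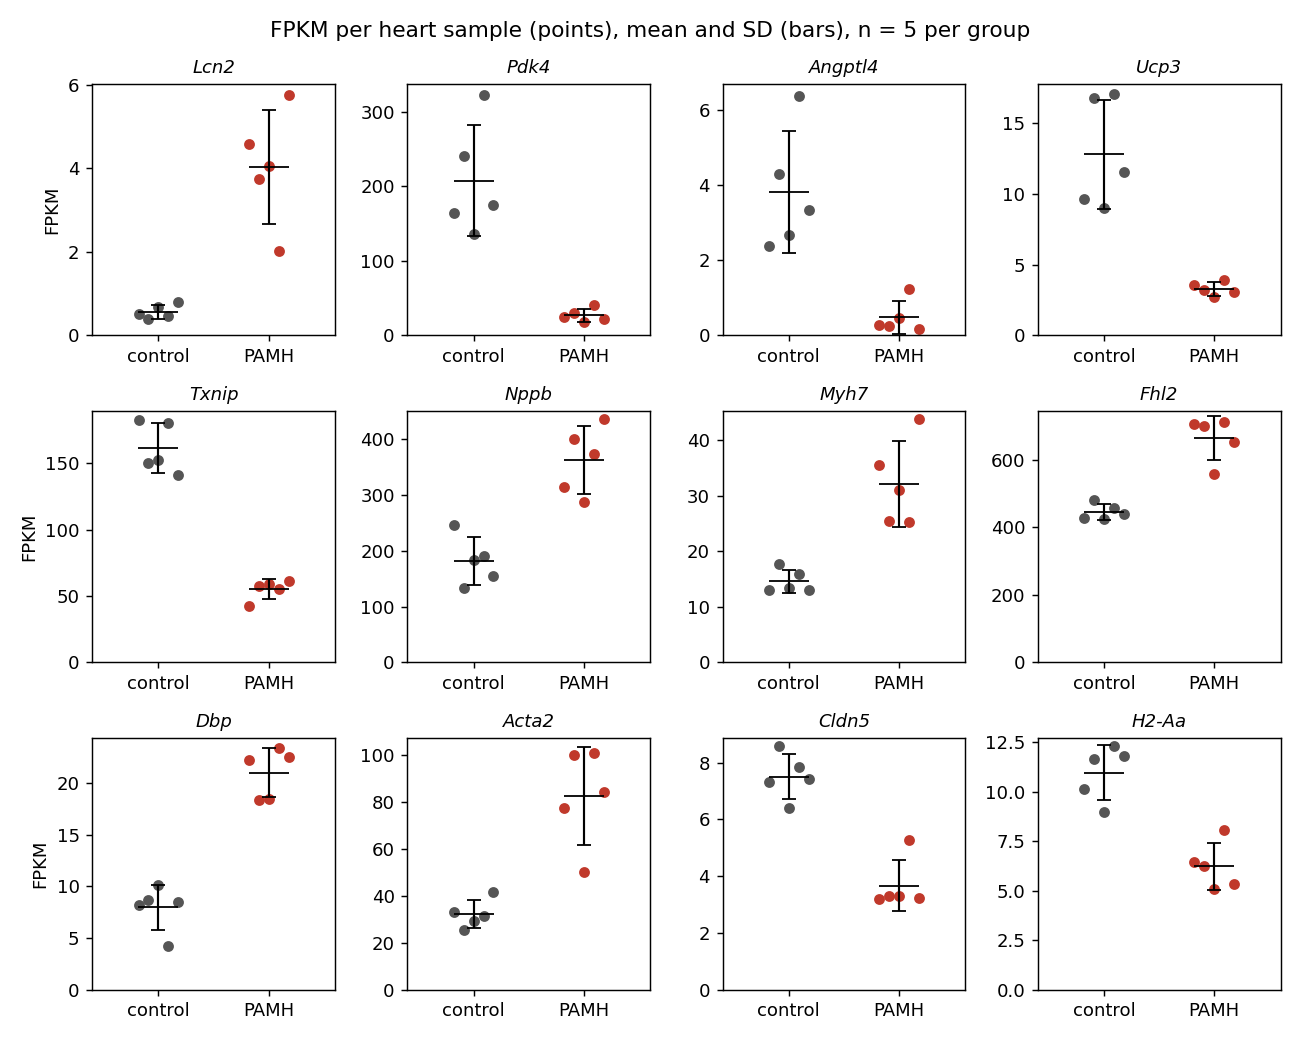
FPKM of 12 genes in each of the 5 control (grey) and 5 PAMH (red) heart samples, with the group mean and SD as bars; every vertical axis is linear and starts at 0. In each panel the groups do not overlap, which the rule for the largest changes required of all these genes except Fhl2 and H2-Aa. Pdk4 averages 208 FPKM in control and 27.0 in PAMH hearts, and Nppb 182 and 362 FPKM.

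Pdk4, Ucp3 and Angptl4 belong to a list that did not move as a whole. Of 33 tested genes of fatty acid uptake and oxidation, 2 were higher (among them Eci2, named after its values were seen), 3 were lower (Pdk4, Ucp3 and Angptl4) and 28 did not pass the test. Adjusted over the list alone, 3 were higher and 3 lower. Its median log2 fold change was 0.08 and its mean -0.05, and camera gave no call (adjusted p = 0.856). Cpt1b, the muscle enzyme that admits long-chain fatty acids to mitochondria, had 93.1 ± 7.30 and 103 ± 13.9 FPKM (adjusted p = 0.400), and the coactivator Ppargc1a had 17.8 ± 4.54 and 12.8 ± 2.25 FPKM (log2 fold change -0.43, SE 0.16, adjusted p = 0.115).

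Of 19 tested genes of the stressed or fetal cardiomyocyte 4 were higher in PAMH hearts. Nppb, which encodes B-type natriuretic peptide (chromosome 4, 147985788 to 147987205), rose from 182 ± 43.2 to 362 ± 60.6 FPKM (log2 fold change 1.01, SE 0.16, adjusted p = 0.00527). Myh7, the slow myosin heavy chain of the fetal mouse ventricle (chromosome 14, 54970684 to 54994626), rose from 14.6 ± 2.10 to 32.2 ± 7.73 FPKM (log2 fold change 1.07, SE 0.15, adjusted p = 0.00223), and Tuba8 rose from 50.4 ± 2.81 to 82.8 ± 15.6 FPKM. Fhl1 was the fourth, and 15 members of the list did not pass (5 higher adjusted over the list alone). Camera called the list higher (adjusted p = 0.0461), but not with an estimated correlation (adjusted p = 0.527 with an estimated correlation), and the call held in 13 of 24 other settings. Among ventricular cardiomyocyte markers 4 of 10 were higher and 6 did not pass (6 higher adjusted over the list alone). Besides Myh7 these were the LIM protein Fhl2, from 445 ± 22.7 to 665 ± 64.5 FPKM, the ventricular transcription factor Irx4, from 4.89 ± 0.568 to 8.58 ± 1.501 FPKM, and Mlf1. This list was called higher (adjusted p = 0.0168; adjusted p = 0.527 with an estimated correlation). Myh7 overlaps the antisense genes Mhrt, which averaged 16.8 FPKM, and Gm31251, and without a stated strand setting their reads cannot be told apart. Nppa, the atrial natriuretic peptide gene beside Nppb, did not pass the test at 83.3 ± 31.8 and 150 ± 65.0 FPKM (log2 fold change 0.81, SE 0.32, adjusted p = 0.150). Neither did the adult myosin gene Myh6, at 1439 ± 212 and 1511 ± 275 FPKM, the calcium pump gene Atp2a2, at 1371 ± 129 and 1313 ± 187 FPKM, or the skeletal actin gene Acta1, at 122 ± 22.2 and 134 ± 39.7 FPKM. The sign of the change of Myh6 and Acta1 turned under some scalings.

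Genes of the ribosome and the proteasome had small log2 fold changes, most of them positive. All 74 cytosolic ribosomal protein genes had positive log2 fold changes in the deposited FPKM, with a median of 0.21 where that of all genes was 0.07. Under other scalings between 64 (quantile normalization) and 74 of them were positive, with medians from 0.09 to 0.26. Of these genes 7 passed the test, 67 did not, and 31 were higher adjusted over the list alone (camera adjusted p = 9.94e-09; adjusted p = 0.616 with an estimated correlation). The largest change among them was that of Rpl3, from 27.5 ± 2.16 to 46.5 ± 6.84 FPKM (log2 fold change 0.73, SE 0.10, adjusted p = 0.00240). Rpl4, Rps27a and Rpl9 had log2 fold changes of 0.29, 0.40 and 0.35, and each lost its call under median ratio scaling. Ribosomal protein genes have many near-identical pseudogene copies, and how their reads were divided is not given. All 31 proteasome genes also had positive log2 fold changes in the deposited FPKM, with a median of 0.15, and 18 with quantile normalization, but 1 of them, Psmc4, passed the test and 30 did not (6 higher adjusted over the list alone; camera adjusted p = 0.00463; adjusted p = 0.527 with an estimated correlation). The proteasome call ended with quantile normalization, where the list's median was 0.02, with the mitochondrial genes left out and with the filter at 5 FPKM. Of 18 genes of heat shock and protein folding 17 had positive changes (12 with quantile normalization) and 1, the HSP90 co-chaperone Ahsa1, passed the test, with 5 higher adjusted over the list alone (camera adjusted p = 0.0360; adjusted p = 0.616 with an estimated correlation). Hspa1b, an inducible HSP70 gene, averaged 0.942 ± 0.432 and 4.26 ± 3.45 FPKM and did not pass (adjusted p = 0.0760), except without PAMH replicate 2.

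Of 18 tested clock genes 6 were higher. Dbp, a transcription factor with strong daily oscillation, rose from 7.95 ± 2.198 to 21.0 ± 2.40 FPKM (log2 fold change 1.33, SE 0.17, adjusted p = 0.00180), and its relative Tef from 8.88 ± 0.575 to 11.99 ± 1.48 FPKM. Bhlhe41 rose from 1.40 ± 0.283 to 2.55 ± 0.338 FPKM and the repressor Cry1 from 1.59 ± 0.134 to 2.35 ± 0.296 FPKM. Bhlhe40 and Hlf, both named after their values were seen, were the others. The calls of Tef and Hlf ended under 3 of 4 other scalings. The remaining 12 genes did not pass, among them Per1, Per2 and Per3 with log2 fold changes of 0.05, 0.41 and 0.45 and Clock and Nr1d1 with -0.33 and -0.23, these 5 also named after their values were seen. Adjusted over the list alone 11 were higher and 1 lower (camera adjusted p = 0.0132; adjusted p = 0.423 with an estimated correlation). The list's call ended without PAMH replicate 3 and with the filter at 5 FPKM (adjusted p up to 0.198). The time of day at tissue collection is not in the labels.

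Camera called the list of genes induced by glucocorticoids lower, though not with an estimated correlation. Of 18 tested members 3 were lower (Pdk4, Angptl4 and Cdkn1a, an inhibitor of the cell cycle), 1 was higher (Lcn2, which encodes lipocalin 2) and 14 did not pass (6 lower and 1 higher adjusted over the list alone). The median log2 fold change was -0.27 (camera adjusted p = 2.49e-06; adjusted p = 0.423 with an estimated correlation). Cdkn1a fell from 13.4 ± 4.65 to 5.60 ± 1.61 FPKM, while Lcn2 rose from 0.563 ± 0.163 to 4.03 ± 1.36 FPKM. Klf15, a glucocorticoid-induced factor, narrowly missed the threshold at 18.7 ± 1.76 and 15.1 ± 1.13 FPKM (adjusted p = 0.0528), and passed in 10 of 24 other settings. Muscle atrophy genes went both ways, with 5 of 13 positive and a median log2 fold change of -0.07. The ubiquitin ligase genes Trim63 and Fbxo32 fell from 52.2 ± 3.96 to 37.5 ± 3.53 and from 16.1 ± 1.53 to 10.9 ± 1.43 FPKM, and the forkhead factors Foxo3 and Foxo1 fell from 10.99 ± 1.11 to 7.73 ± 0.832 and from 2.45 ± 0.233 to 1.75 ± 0.151 FPKM. Bnip3, named after its values were seen, rose (log2 fold change 0.55). These were the 4 lower and 1 higher of the 13 tested atrophy genes, and 8 did not pass; adjusted over the list alone 5 were lower and 3 higher (camera adjusted p = 0.0146; adjusted p = 0.423 with an estimated correlation). In the insulin and growth factor list 2 of 24 genes were lower, again Foxo3 and Foxo1, and 22 did not pass (2 lower and 1 higher adjusted over the list alone). Its camera call was downward (adjusted p = 0.0456; adjusted p = 0.527 with an estimated correlation) although its median was 0.01 and its mean -0.03.

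Of 13 tested basement membrane genes 3 were lower, and of 24 endothelial markers 2 were lower. Lama5, a laminin chain, fell from 8.78 ± 0.883 to 5.89 ± 0.835 FPKM, Nid2 from 2.17 ± 0.292 to 1.54 ± 0.118 FPKM and Col4a1 from 41.4 ± 7.18 to 29.2 ± 4.69 FPKM. Nid2 lost its call in 11 of 23 other settings and Col4a1 in 11 of 24 (limma adjusted p up to 0.0893 and 0.141). The other 10 basement membrane genes did not pass, and 5 were lower adjusted over the list alone (median log2 fold change -0.13; camera adjusted p = 1.09e-05; adjusted p = 0.423 with an estimated correlation). Nid2 overlaps Rtraf on the opposite strand, and Col3a1 overlaps Gm47302, which averaged 21.6 FPKM, on the same strand. The values of Nid2 and Col3a1 are therefore uncertain. Col4a1 overlaps Col4a2 on the opposite strand only at the ends of the genes (chromosome 8, 11312805 to 11312826). Of the endothelial markers 22 did not pass and 10 had positive changes, with 3 lower adjusted over the list alone (camera adjusted p = 0.000424; adjusted p = 0.490 with an estimated correlation). Cldn5, a tight junction protein, fell from 7.51 ± 0.797 to 3.66 ± 0.906 FPKM (log2 fold change -0.88, SE 0.12, adjusted p = 0.00200), and Gpihbp1, which holds lipoprotein lipase on capillaries, from 19.99 ± 1.99 to 13.7 ± 1.93 FPKM. The marker Pecam1 had 17.99 ± 1.37 and 15.2 ± 1.53 FPKM (adjusted p = 0.106), and passed in 3 of 24 other settings. In the wider matrix and fibrosis list 1 of 30 genes was lower and 29 did not pass, with 1 lower adjusted over the list alone (camera adjusted p = 0.0132; adjusted p = 0.704 with an estimated correlation). The median of that list was -0.02 and turned positive when each sample was rescaled to the same FPKM sum. Col1a1, Col3a1, Postn and Tgfb1 did not pass, with log2 fold changes of -0.07, -0.33, -0.10 and 0.05, though Col3a1 passed in 7 of 24 other settings. Fibroblast markers (19 tested) and skeletal muscle markers (7 tested) had no member past the threshold, over all genes or adjusted over the list alone. Their camera calls were downward (adjusted p = 0.0453 and 0.0288; adjusted p = 0.527 and 0.423 with an estimated correlation). At an unadjusted p under 0.05, 2264 of all 9439 genes passed in limma.

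Of 13 tested antigen presentation genes 2 were lower, both of class II: H2-Aa fell from 10.97 ± 1.38 to 6.23 ± 1.19 FPKM and H2-Ab1 from 11.8 ± 0.601 to 7.26 ± 1.70 FPKM. The invariant chain gene Cd74 averaged 34.0 ± 4.01 and 25.8 ± 12.8 FPKM, with 48.5 FPKM in PAMH replicate 4 and 18.1 to 22.4 FPKM in the other PAMH samples; it did not pass, but fell without PAMH replicate 4. In this list 11 genes did not pass, with 2 lower adjusted over the list alone (camera adjusted p = 0.00463; adjusted p = 0.616 with an estimated correlation). None of 22 interferon response genes passed singly, either over all genes or adjusted over the list alone, though 18 had negative changes and camera called the list lower (adjusted p = 0.000424; adjusted p = 0.527 with an estimated correlation). Among them Rsad2 averaged 2.51 ± 0.706 and 1.43 ± 0.576 FPKM (adjusted p = 0.0772), and it passed without PAMH replicate 3. All 13 protein-coding genes of the mitochondrial genome had negative changes in the deposited FPKM (6 were positive with quantile normalization and 1 when each sample was rescaled to the same sum), with a median of -0.09, and none passed singly, over all genes or adjusted over the list alone (camera adjusted p = 0.000424; adjusted p = 0.527 with an estimated correlation; no call with quantile normalization). With 7 nuclear copies on chromosome 1 the mitochondrial genes held 73.7% to 79.7% of each FPKM sum, and their reads cannot be separated from those of the copies.

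**Figure D2:**
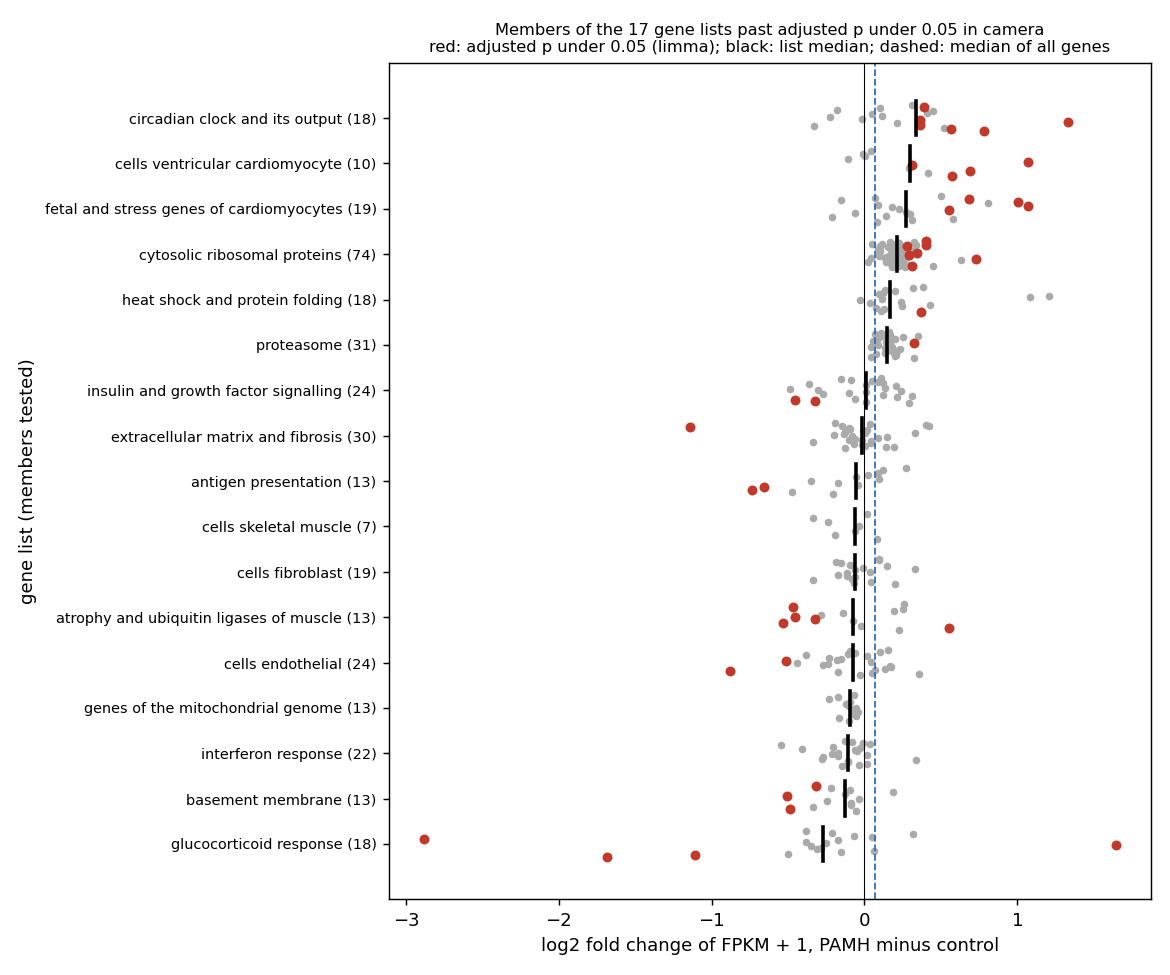
Log2 fold change (FPKM + 1, PAMH minus control) of each tested member of the 17 gene lists called by camera with the preset correlation; red points passed limma's test, grey points did not, black bars are list medians and the dashed line is the median of all tested genes (0.07). Ribosomal protein genes lie to the right of 0 in all 74 cases (64 with quantile normalization), and Pdk4 at -2.88 and Lcn2 at 1.64 are the extremes of the glucocorticoid list.

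Other large rises followed. Acta2, smooth muscle actin, rose from 32.1 ± 5.95 to 82.5 ± 20.7 FPKM (log2 fold change 1.31, SE 0.18, adjusted p = 0.00223), the prostaglandin D synthase gene Ptgds from 79.0 ± 15.01 to 192 ± 42.5 FPKM, and the transferrin receptor gene Tfrc from 8.77 ± 1.59 to 19.2 ± 1.10 FPKM. Acta2 was the 1 of 15 smooth muscle and pericyte markers that passed (4 higher adjusted over the list alone), and camera did not call that list (adjusted p = 0.962). The mesothelial marker Upk3b rose from 0.293 ± 0.139 to 2.04 ± 0.787 FPKM. Only 3 epicardial and mesothelial markers were above the filter, too few for a list test. Of the others, both named after their values were seen, Aldh1a2 was also higher (log2 fold change 0.62, adjusted p = 0.00904 by limma) and Aldh1a1 did not pass. Rtn4r rose from 1.96 ± 0.486 to 5.66 ± 1.27 FPKM, the stress-induced gene Ier3 from 8.01 ± 1.94 to 18.8 ± 1.94 FPKM, and G0s2, an inhibitor of adipose triglyceride lipase, from 14.2 ± 1.98 to 32.3 ± 12.4 FPKM. Further falls were those of Tmem82, Arrdc2, Chac1, Slc41a3 and Tacc2, with log2 fold changes between -0.98 and -0.78. Of the receptors bearing on the treatment, the AMH receptor gene Amhr2 was listed at 0 in all 5 PAMH and 2 control samples and at 0.0186, 0.0459 and 0.0747 FPKM in control replicates 1, 2 and 3. The estrogen receptor gene Esr1, listed at up to 0.0396 FPKM, was also below the filter, and neither was tested.

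The share of higher genes depended on scaling. When each sample was rescaled to the same sum 563 genes were higher and 85 lower, and with the trend on transcript length and GC content removed and each sample's mean kept 726 and 141. With median ratio scaling 214 genes were higher and 189 lower, with quantile normalization 234 and 246, with the mitochondrial genes left out 216 and 202, and with the length and GC trend removed with centring 329 and 250. With 1 sample left out the count of changed genes ranged from 278 without control replicate 3 to 1126 without PAMH replicate 3. The calls of the fetal and stress, heat shock, fibroblast, skeletal muscle, matrix, atrophy, insulin and clock lists each ended on omission of a single sample. No list kept its call when camera used an estimated correlation (0 of 51, smallest adjusted p = 0.423). With the preset correlation 17 lists were called, against 9 by fry in a common direction and 36 by fry in either direction. In a common direction fry called the ribosomal, proteasome, clock, ventricular and fetal lists. Lists of atrial markers, TGF-beta and BMP signalling, steroid and AMH receptors and related enzymes, and complement were called by fry but not by camera. The glucocorticoid, basement membrane, endothelial, interferon, antigen presentation and mitochondrial genome lists were not called by fry (adjusted p = 0.063 to 0.366). Fry does not compare a list with other genes and was run only on the deposited FPKM, where the median of all genes was 0.07. Such an offset favours upward calls and works against downward ones. All 9 lists that fry called in a common direction had positive medians.

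**Figure D3:**
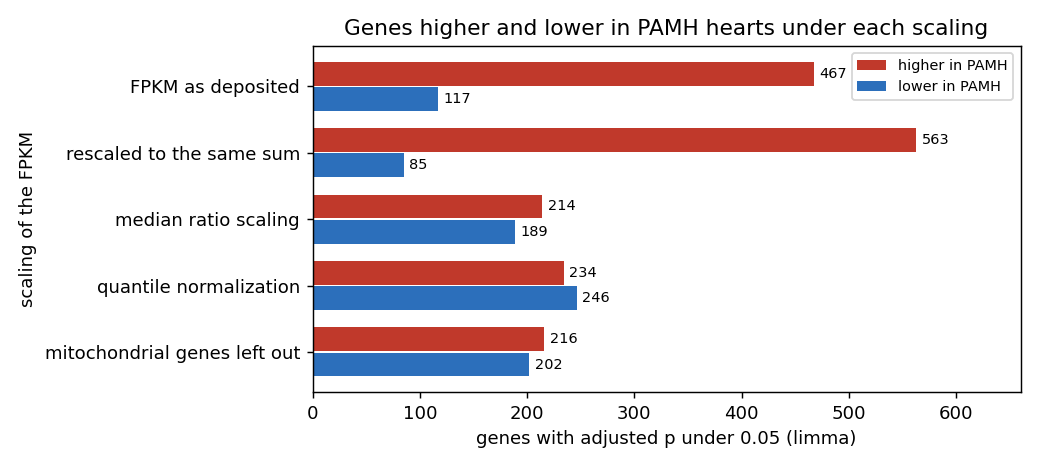
Number of genes higher (red) and lower (blue) in PAMH hearts at an adjusted p under 0.05 in limma, for the FPKM as deposited and for 4 other scalings; the horizontal axis starts at 0. The higher genes number 467 in the deposited FPKM, 563 after rescaling to the same sum and 214 to 234 under median ratio scaling, quantile normalization and omission of the mitochondrial genes, with 189 to 246 lower.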

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

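The tests with the mitochondrial genes left out, of length and GC content and of PAMH replicate 4 for the excess of higher genes, of the daily cycle and of the PPAR targets were chosen or changed only after the result was seen. The other tests were set before, though their limits named no interval or standard error. Among 194 sets of 5 samples, 17 had a sample far from the other 4 of its group, against 9.7 expected by chance, and 9 of the 17 were in PAMH replicate 4 and 5 in control replicate 2. PAMH replicate 4 had a hemoglobin sum of 859 FPKM (97.1 to 249 in the others) and a rank correlation with the median sample of 0.946. It also had the highest PAMH values of Ier3 (22.2 FPKM), Angptl4 (1.24 FPKM), Cldn5 (5.28 FPKM), Cd74 (48.5 FPKM), Ahsa1 (16.5 FPKM) and Stip1 (58.9 FPKM) and the lowest of Fbxo32 (8.36 FPKM). Control replicate 2 had the highest control values of Ier3 (11.4 FPKM), Eno3 (521 FPKM), Myh6 (1810 FPKM), Atp2a2 (1599 FPKM) and Cpt1b (105 FPKM). The remaining such values were Rpl3 in control replicate 3 (31.2 FPKM), Mlf1 in control replicate 1 (47.9 FPKM) and Cacna1s in control replicate 4 (1.14 FPKM).

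Most changed genes were higher in PAMH hearts (467 of 584, or 79.97%). The tables argue against PAMH replicate 4 as the source, since 79.0% of the changed genes were higher without it. A trend on length and GC content stays open, since removing it gave 83.7% with each sample's mean kept, which keeps the offset between the groups, and 56.8% with centring, which removes that offset, so neither form decides. A lower share of mitochondrial transcripts also stays open: 51.7% of the changed genes were higher with these genes left out and the rest rescaled and 53.1% with median ratio scaling, but both scalings set the level of the remaining genes and so decide nothing. It cannot be told apart from a broad rise of nuclear transcripts in PAMH hearts, which the design allows as a biological difference, because FPKM are relative to the whole library.

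Camera with the preset correlation called the ribosomal protein list higher and the basement membrane list lower, with a difference between the mean log2 fold changes of the lists of 0.41 (SE 0.10); neither call held with an estimated correlation (adjusted p = 0.616 and 0.423 with an estimated correlation). Trends on length and GC content do not account for it, since the difference was 0.37 (SE 0.08) after their removal, nor does PAMH replicate 4, without which it was 0.37 (SE 0.11). A lower share of endothelial cells, which make much of the basement membrane, could not be decided. Of 24 endothelial markers 75.0% (95% exact interval 53.3% to 90.2%) lay under the median of all genes. Their median minus that of all genes was -0.15. Both fell short of the limits set beforehand (80% and -0.2), which by themselves would count against this explanation. The interval includes 80%, but it was not part of those limits and treats the markers as independent. An effect of the prenatal treatment on these genes stays open.

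Pdk4, Ucp3, Angptl4 and Txnip fell together. PAMH replicate 4 does not account for this. It had the highest PAMH values of Pdk4 (40.4 FPKM), Ucp3 (3.90 FPKM) and Angptl4 (1.24 FPKM), nearest to the controls. Its Txnip (55.1 FPKM) lay within the range of the other PAMH samples. Without it the highest adjusted p of the 4 genes was 0.000661 by limma, an outcome that these values made likely beforehand. A list of 22 tested PPAR targets, which left out these 4 genes, did not fall as a set, with a median log2 fold change of 0.073 and 18 positive. In limma 1 of these targets passed as higher and 1 as lower. Their median was close to that of all tested genes (0.0713), and the 95% bootstrap interval (0.051 to 0.142) came from genes, not samples. The values therefore do not exclude a fall limited to some PPAR targets. A different time of the daily cycle at collection stays open. The mean log2 value of 8 clock genes grouped with Dbp, minus that of 5 grouped with Arntl, was higher by 0.55 in PAMH hearts. These genes were grouped after several clock genes had been seen to be higher. The difference therefore restates that observation and does not bear on the cause. On the genes above the filter, which leaves out Arntl and Npas2, the difference was 0.41. Nr1d1 (log2 fold change -0.23, adjusted p = 0.261 by limma) and Cry1 (0.36) each changed against the direction of the difference, which does not decide the time of collection. Feeding state was not tested, and an effect of the prenatal treatment on the clock or on these genes stays open.

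For the number of changed genes, 100 splits of the 10 samples into 5 and 5 were compared. Of these 1, the real one, gave 584 genes or more, and the highest other gave 433. That split exchanged control replicate 2 and PAMH replicate 3, and the next highest gave 2 genes. So many changed genes were thus rare among groupings of these samples. Such splits cannot exclude differences between litters or dams, which the labels do not give. For lists called by camera with the preset correlation, 1 of the 100 splits, the real one, gave 17 or more, the highest other gave 15 and the median of the 99 others was 7, so a call of a list by itself carries little weight. On the 1126 genes called without it, PAMH replicate 3 lay nearer to the control mean for more genes than to the PAMH mean (39.8% nearer to PAMH), yet it was on the PAMH side of all 5 controls for 56.3% of them and had the lowest Pdk4 and Ucp3 of all 10 samples. Control replicate 2 lay nearer to its own group for 80.6% of the 464 genes called without it.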

How the results depend on the processing

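Of the settings below, omission of the mitochondrial genes, omission of PAMH replicates 4 and 5, both removals of the length and GC trend and protein-coding genes only were chosen after seeing the data. Each change in a count is given without a cause, since the cause was not tested. Depth is unknown and limits what can be said of genes with low FPKM.

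Without a filter 264 genes changed (196 higher, 68 lower; 26758 tested), and with a filter at 5 FPKM 75 were lower. Rescaling each sample to the same sum gave 563 higher and 85 lower genes. Median ratio scaling gave 214 higher and 189 lower genes, quantile normalization 234 and 246, and omission of the mitochondrial genes 216 and 202. Sample weights gave 1214 genes (1038 higher, 176 lower), and without PAMH replicates 4 and 5 there were 360 (279 higher). Removing the length and GC trend gave 726 higher genes, and with centring 250 lower genes. The replicate number as a block gave 239 genes (175 higher, 64 lower); the numbers do not pair the samples, since the correlations of same-numbered deviations were 0.09, 0.16, -0.04, -0.19 and -0.04, and of the controls only replicate 1 matched its own number best. No list passed with an estimated correlation (0).

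Leaving out each sample in turn gave 278 to 1126 changed genes, 206 to 979 higher, 69 to 147 lower and 11 to 17 lists. The count moved by more than 1.5 times without control replicates 1 (302), 3 (278), 4 (305) and 5 (297) and PAMH replicates 1 (311), 3 (1126) and 5 (345). Of the 1126 genes, 573 were among the 584.

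Of 48 called named genes 29 kept their call in every setting they entered (at most 24), 19 lost it in some and 0 reversed. Those lost most often were Rpl9, Psmc4, Ahsa1 and Fhl1. Of 41 named genes that had not passed, 19 passed in some setting (most often Klf15, in 10) and 6 turned sign in some. Median ratio scaling gave -0.021 for Myh6 and -0.013 for Tgfb1, and quantile normalization -0.022 for Tgfb1. With the mitochondrial genes left out Myh6 was at -0.052, Acta1 at -0.030 and Tgfb1 at -0.037, and with the trend removed with centring at -0.052, -0.036 and -0.063. Without PAMH replicates 4 and 5 Postn was at 0.025 and Tgfb1 at -0.018. Leaving out each sample in turn, Myh6 ranged from -0.018 (without PAMH replicate 4) to 0.148, Acta1 from -0.021 (without PAMH replicate 3) to 0.294, Col1a1 from -0.148 to 0.061 (without PAMH replicate 3) and Casq1 from -0.187 to 0.054 (positive without control replicate 2 and, at 0.025, without PAMH replicate 2).

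Lists of ribosomal proteins, glucocorticoid response, basement membrane, antigen presentation and endothelial markers were called in all 24 settings with the preset correlation, and interferon response in all 23 it entered. Ventricular markers were called in 23, mitochondrial genes in 22 of 23, atrophy and the clock in 22, the proteasome in 21, matrix in 19, skeletal muscle in 18 of 23, fibroblast in 17, heat shock in 16, and fetal and stress genes and insulin signalling in 13. Without PAMH replicate 3 the calls of the clock, atrophy, matrix, fibroblast, heat shock, insulin and fetal lists ended. The matrix call also ended without control replicate 2, the insulin and heat shock calls without control replicates 2 and 3 (heat shock also PAMH replicate 4), the fibroblast call without control replicates 2, 3 and 5, the skeletal muscle call without control replicates 2 and 3 and PAMH replicates 2 and 4, and the fetal call without control replicates 4 and 5 and PAMH replicates 1, 2 and 4.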

Other observations

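Several gene groups that camera did not call held members that changed, each named after its values were seen except Ier3, Chac1 and Lcn2. Glycolytic genes Hk1 (log2 fold change 0.65, SE 0.13, adjusted p = 0.0159 by limma), Pgam1 (0.62) and Pfkp (0.28) were higher, 3 of 23 tested (4 adjusted over the list alone). Among genes of angiogenesis and hypoxia Egln3 (0.60), Bnip3 (0.55), Pdgfa (0.52) and Adm (0.44) were higher and Apln (-0.43) lower, of 23 tested. Of 20 channel genes 3 were higher, among them the potassium channel genes Kcnh2 (0.55) and Kcnj5 (0.42). The nuclear receptor gene Esrra (0.46) and the mitochondrial import genes Timm23 (0.36) and Tomm20 (0.23) were higher, 3 of 20 genes of mitochondrial biogenesis. Hsd11b1, whose enzyme regenerates active glucocorticoid within cells, was higher (0.69, SE 0.09, adjusted p = 0.00206) while camera called the glucocorticoid response list lower only with the preset correlation (adjusted p = 2.49e-06; adjusted p = 0.423 with an estimated correlation). In the sarcomere list Tcap (0.42) was the only member of 22 that passed.

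Immediate early genes moved apart: Ier3 (1.16) and Nr4a1 (1.05) were higher and Zfp36 (-0.71) lower, of 19 tested. The chemokine gene Ccl7 (0.90) was higher, as was Lcn2, and the other 10 of 12 tested genes of cytokines and chemokines did not pass. The complement gene C3 (0.75) was the 1 of 16 complement genes that passed, and Cd68 (0.46) the 1 of 19 macrophage markers, of which 11 had positive changes. In the stress response list Chac1 (-0.85) and Herpud1 (-0.40) were lower and Pdia6 (0.45) higher, of 21 tested. Of 23 autophagy genes Gabarapl1 (-0.43) and Wipi1 (-0.28) were lower, Bnip3 (0.55) was higher and 20 did not pass. The alpha-1A adrenergic receptor gene Adra1a (-0.53) was lower, while Ednra (0.32) and Adcy5 (0.38) were higher, and 16 of the 19 tested genes of adrenergic and angiotensin signalling did not pass. Of 84 called members over all lists, all 84 kept their sign under 4 other scalings and 49 kept their call in all of them. Bnip3, Pfkp, Kcnj5, Tomm20, Timm23, Tcap, Cd68, Adm, Pdia6, Ednra and Adcy5 are among those that lost it in at least 2. Eci2 and Mlf1, described above as higher, also lost their call in at least 2.

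Arntl, which encodes the activating partner of Clock, averaged 0.992 ± 0.284 FPKM in control and 0.386 ± 0.233 FPKM in PAMH hearts (SD, n = 5 each) and lay below the filter, so it was not tested. Nnt, which encodes a mitochondrial transhydrogenase, is listed under 2 gene identifiers, and the first held 100% of their joint FPKM in 7 samples but 2.67%, 2.84% and 7.53% in control replicate 2, PAMH replicate 1 and PAMH replicate 5. Sept2 is also listed under 2 identifiers, and the first held between 4.54% and 100% of the joint FPKM.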
